A study of Homo sapiens with 4 samples.

How the data were processed

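RNA was sequenced from SCC1 and FaDu cells given FOSL1 siRNA or control siRNA, with 1 library in each of the 4 groups, and per the labels' protocols the libraries were made with a KAPA RNA-Seq kit. Per the submitters' processing notes, TopHat, Cufflinks and genome build hg18 were used; their roles and versions, the read counter, the normalization, the strand setting and the siRNA sequences are not given in the sources used here. Genome positions are not printed, since the annotation used here is of build GRCh38.

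The authors deposited 1 table per line, of genes that passed their own comparison. The 2 expression columns of each table hold CPM, per the file headers and the values: 100% of the deposited CPM values were whole multiples, within 0.01 of a step, of what 1 read is worth in that library (0.0755 CPM for the SCC1 control, 0.0886 for SCC1 with FOSL1 siRNA, 0.0871 for the FaDu control and 0.0965 for FaDu with FOSL1 siRNA). Reads per gene were recovered from these steps. The effective library sizes are given in the report; raw read totals could not be worked out from them. The deposited score is a signed linear fold, negative where FOSL1 siRNA was lower, and the authors' p-value and FDR stand beside it per the file headers. The name of the SCC1 control column ends in a 2 that the labels do not explain.

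Each deposited p-value was under 0.05. From the ratio of FDR to p-value, the authors tested 13796 genes in each line, and the last listed gene ranked at most 2003 in SCC1 and 1639 in FaDu, so up to 100 and 94 genes past that threshold were not analysed here. The authors' deposited p-values lay within 1% of edgeR's likelihood ratio test at an assumed dispersion of 0.05 for 1903 of 1903 genes in SCC1 and 1545 of 1545 in FaDu, when that test was run on the recovered reads (edgeR 4.0.16 in R 4.3.3). A test on the reads of 2 libraries compares those libraries, not the conditions, and its result depends on the assumed dispersion.

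Folds were taken as ratios of CPM with no pseudocount, and genes of at least 1.5-fold were counted as higher or lower, which all listed genes met. A ratio with reads in both libraries has an exact binomial interval at 95% confidence; against a library at 0 reads the fold was computed at a floor of 3 reads and is a lower bound. The design foresaw another unit as possible, so its level rule of 5 was applied on the CPM scale. No p-value of any list or gene was computed across genes, and lists drawn at random to match expression could not be used in a table of filtered genes. Computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

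Before the data were examined, 29 gene lists, the alternatives and the rule for naming genes were fixed. The rule takes FOSL1; in each line the 12 largest rises and 12 largest falls on log2(CPM + 1) among genes reaching 5 CPM, leaving out small RNAs and rows with several symbols; across lines the 8 largest shared rises, 8 largest shared falls and 8 opposite genes; up to 4 members per list; and 11 preset names. Some genes that the rule takes are not reported here. The lists cover AP-1, epithelial-mesenchymal transition, junctions, proteases, integrins, basal and differentiated keratinocytes, both cell cycle phases, p53 targets, interferon-stimulated genes, antigen presentation, cytokines, EGFR and MAPK, YAP/TAZ, hypoxia, cholesterol, ATF4, NRF2, TGF-beta, stemness, Mediator, metallothioneins, histones, ribosomal and mitochondrial genes, and markers of fibroblasts, leukocytes and endothelium. A gene in several lists counts in each.

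Recovery of reads was tested on simulated data: 100% of the reads came back in both lines, and the intervals covered the true ratio for 95.5% of 1903 genes in SCC1 and 95.7% of 1545 in FaDu. Those data were whole reads with Poisson error and no further dispersion, so this checks the computation only. In simulated libraries of those genes with 200 changed by 4-fold, the count test at dispersion 0.05 found 95.5% of the changed genes in SCC1 and 92.5% in FaDu, and called 5.05% and 5.95% of the others. With a simulated dispersion of 0.16 it found 89.5% and 82.5%, and called 26.5% and 22.2% of the others. Alternatives were a fold of 2, pseudocounts of 1 and 0.1 CPM, level minimums of 1 and 5 CPM, rows of one symbol summed, older symbols, stricter p-values and FDR, scaling to the median fold of listed genes, and, chosen after seeing the data, an FDR under 0.05, the count test at other dispersions, and leaving out genes at 0 reads and readthrough models.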

Results

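RNA-seq profiles of total RNA were compared between cells given a siRNA against FOSL1 and cells given a control siRNA, in 2 human head and neck squamous cell carcinoma lines, SCC1 and FaDu. FaDu is an established line from a squamous carcinoma of the hypopharynx. FOSL1 encodes FRA1, a subunit of the AP-1 transcription factor. Each line had 1 library per group, taken 48 h after treatment, so the differences have no replicate check within a line, and no test across conditions was made. The effective library sizes, worked out from the value that 1 read has in each column, were 13242163 reads for the SCC1 control, 11280745 for SCC1 with FOSL1 siRNA, 11477600 for the FaDu control and 10365774 for FaDu with FOSL1 siRNA. The tables list part of the genes, and a gene outside them is not called unchanged. Values in parentheses after a fold are 95% exact binomial intervals. They cover counting error only, with each read taken as an independent molecule. PCR reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for that error. A narrow interval does not show a difference between conditions, and in each line most listed genes had an authors' FDR above 0.05.

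FOSL1 was 33.2-fold lower in the SCC1 library with FOSL1 siRNA (24.7 to 45.7), at 3.99 CPM (reads scaled to the library size) against 133 CPM in its control. In FaDu it was 20.9-fold lower (18.9 to 23.3), at 36.9 CPM against 774 CPM. The target therefore moved in the direction that the labels give in both lines. The authors' deposited table gave FOSL1 an FDR of 1.67e-15 in SCC1 and 3.28e-13 in FaDu. Among the 19 AP-1 family members, the other listed gene in SCC1 was ATF2, 2.26-fold lower (1.97 to 2.59). In FaDu, 5 members were lower (1 after scaling to the median fold, FOSL1 itself) and 1 was higher, with ATF3 2.74-fold lower (2.37 to 3.18), ATF2 2.64-fold lower (2.30 to 3.04) and JUN 2.28-fold lower (2.11 to 2.45). The authors' deposited table gave ATF2 an FDR of 0.165 in SCC1 and 0.0832 in FaDu, ATF3 0.0665 and JUN 0.175. FOSL2 and JUNB were in neither table.

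**Figure D1:**
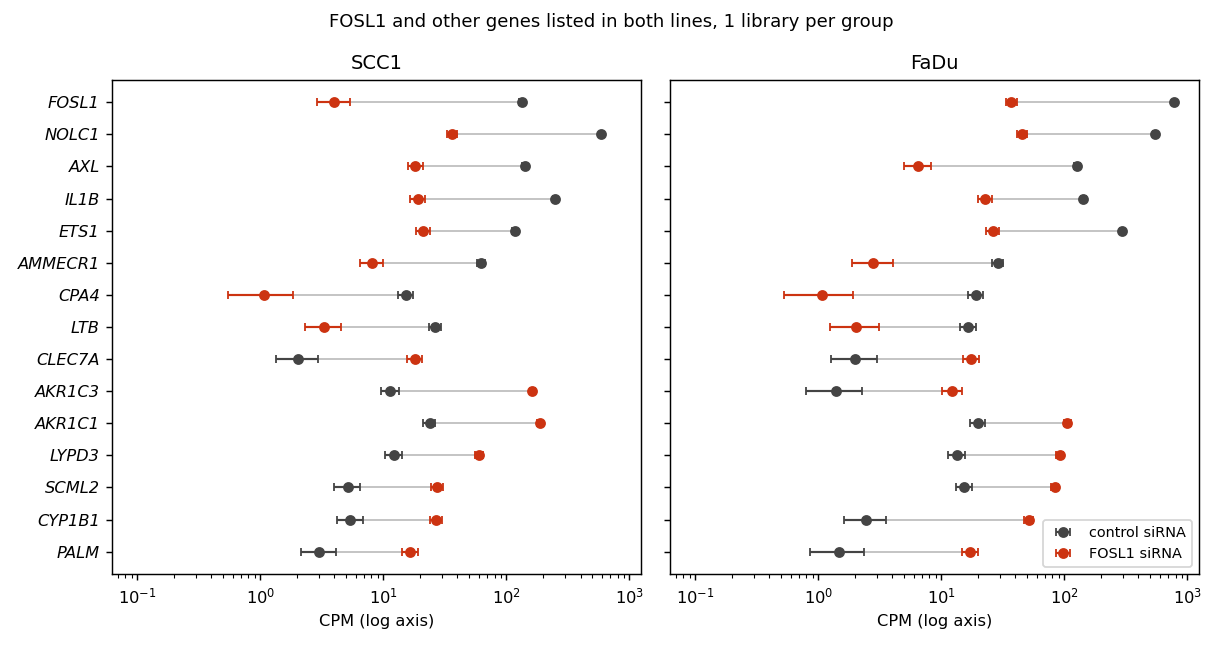
CPM on a log axis of FOSL1 and 14 other genes listed in both lines, in the control siRNA library (dark) and the FOSL1 siRNA library (red) of SCC1 and FaDu. Each point is 1 library and each bar its 95% Poisson counting interval; FOSL1 went from 133 to 3.99 CPM in SCC1 and from 774 to 36.9 CPM in FaDu.

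The first comparison asks which transcripts differ in SCC1 cells after depletion of FOSL1. NOLC1, which encodes a nucleolar phosphoprotein, was 16.3-fold lower (14.7 to 18.0), going from 588 to 36.2 CPM. The inflammatory cytokine gene IL1B was 13.1-fold lower (11.4 to 15.1), and the plasminogen activator inhibitor gene SERPINB2 was 11.6-fold lower (8.86 to 15.5). Genes that were higher included the aldo-keto reductase genes AKR1C3, 14.3-fold higher (12.1 to 17.0), AKR1C2, 9.63-fold higher (7.80 to 12), and AKR1C1, 7.84-fold higher (6.96 to 8.85). These 3 genes are closely related copies, so their separate values are uncertain.

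The table for SCC1 lists 1903 genes, 773 higher and 1130 lower after FOSL1 siRNA, none closer to 1 than 1.88-fold. These are 13.8% of the 13796 genes that the authors tested. About that share of a gene list would be listed without any link to it, if all of its members were tested. At least 4-fold differences were seen for 158 genes that were higher and 197 that were lower. Among the other large falls, APLN, which encodes the peptide ligand apelin, was 17.2-fold lower (11.4 to 27.1). The carboxypeptidase gene CPA4 was 14.3-fold lower (8.03 to 28.2), and the vitamin D hydroxylase gene CYP24A1 was 8.91-fold lower (7.30 to 11). CSF3, the gene of granulocyte colony-stimulating factor, had 193 reads in the control and 1 read after FOSL1 siRNA, a ratio of 164 (29.2 to 6527). Among the other large rises, STC1, encoding the secreted glycoprotein stanniocalcin, was 22.0-fold higher (10.9 to 51.9) and PALM3 19.2-fold higher (10.5 to 39.2). BBOX1, an enzyme of carnitine synthesis, was 17.4-fold higher (8.17 to 44.5), and SNAI1, a repressor of epithelial genes, was 9.39-fold higher (6.01 to 15.4). The receptor gene CLEC7A was 8.87-fold higher (5.92 to 13.8) and the ligand gene TNFSF9 8.27-fold higher (5.97 to 11.7). CSF1, the gene of macrophage colony-stimulating factor, rose from 31.9 to 238 CPM, and the noncoding RNA gene TINCR from 6.95 to 51.6 CPM.

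Some of the largest values belong to genes with near-identical copies. SMN2 had 66.2 CPM in the SCC1 control and no reads after FOSL1 siRNA, at least 249-fold lower by a floor of 3 reads per library, while its copy SMN1 was 6.98-fold higher (5.94 to 8.24). NOMO3 was at least 60.8-fold lower, and EIF3CL at least 34.9-fold lower. The pseudogene GTF2IP4 had 688 reads in the control and 1 after FOSL1 siRNA, a ratio of 586 (105 to 23183). These values are uncertain, because reads can be divided among copies.

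Among 24 targets of NRF2, the regulator of antioxidant genes, 13 were higher, 1 was lower and 10 were not listed in SCC1. OSGIN1 was 4.77-fold higher (3.90 to 5.87), while the cystine transporter gene SLC7A11 was 2.34-fold lower (2.17 to 2.53). The higher genes include the AKR1C genes above, which are not clearly separate members. Of 24 integrin and basement membrane genes, 5 were lower (4 after scaling to the median fold), 0 higher and 19 not listed. ITGA3 was 6.02-fold lower (5.69 to 6.37), ITGB4 4.10-fold lower (3.85 to 4.37), ITGB1 3.88-fold lower (3.69 to 4.08), and CD44 2.50-fold lower (2.38 to 2.63). Of 23 YAP/TAZ targets, 9 were lower (3 after scaling), 0 higher and 14 not listed, among them AXL, 7.73-fold lower (6.69 to 8.98), and CYR61, 3.63-fold lower (3.18 to 4.16). Of 27 EGFR ligands and MAPK feedback genes, 7 were lower (2 after scaling), 0 higher and 20 not listed, with EGR1 6.21-fold lower (5.10 to 7.62) and NRG1 3.01-fold lower (2.79 to 3.25). The cytokine list of 36 had 10 lower (4 after scaling), 2 higher and 24 not listed, with TNFSF15 4.37-fold lower (3.31 to 5.87) beside IL1B and CSF3.

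Of 36 G1/S and replication genes, 14 were lower, 1 was higher and 21 were not listed, with CDK6 4.24-fold lower (3.68 to 4.91), E2F2 3.01-fold lower (2.32 to 3.94) and POLA1 2.99-fold lower (2.50 to 3.60). CDC45, the next largest fall at 2.70-fold (2.43 to 2.99), already had an authors' FDR above 0.05. Of 36 G2/M genes, 3 were lower and 33 not listed: ANLN at 2.09-fold (1.98 to 2.20), DLGAP5 at 2.07-fold (1.89 to 2.26) and TOP2A at 1.99-fold (1.91 to 2.07). At the share of all tested genes that were listed, 4.97 genes of each list of 36 would be listed. Scaling to the median fold left 1 higher and 1 lower G1/S gene, and turned the sign of DLGAP5 and TOP2A. Of 39 interferon-stimulated genes, 10 were lower (3 after scaling), 0 higher and 29 not listed, with CMPK2 4.22-fold lower (2.71 to 6.85), MX2 3.78-fold lower (2.77 to 5.25) and IRF7 3.72-fold lower (3.15 to 4.42). Of 31 hypoxia and glycolysis genes, 7 were higher, 1 was lower and 23 not listed. EGLN3 was 5.07-fold higher (4.41 to 5.85) and CA9 3.73-fold higher (2.65 to 5.34), while DDIT4 was 2.31-fold lower (2.23 to 2.40).

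Of 26 epithelial junction genes, 5 were higher, 1 was lower (0 after scaling) and 20 were not listed in SCC1, with TJP3 3.79-fold higher (2.64 to 5.54), OVOL1 3.72-fold higher (2.76 to 5.09) and CLDN4 3.05-fold higher (2.74 to 3.41). Of 26 regulators and markers of epithelial-mesenchymal transition, 4 were lower, 3 higher and 19 not listed, and scaling to the median fold turned this to 1 lower and 3 higher. VIM was 4.24-fold lower (3.33 to 5.46), THBS1 3.02-fold lower (2.81 to 3.25) and SNAI2 2.07-fold lower (1.80 to 2.38), the last with its sign turned by that scaling. Of 31 proteases and their regulators, 3 were lower, 2 higher and 26 not listed, with PLAT 7.63-fold lower (5.90 to 10.0) and MMP12 2.45-fold higher (2.17 to 2.77). Of 15 basal keratinocyte genes, 2 were lower, 1 higher and 12 not listed, with NGFR 6.03-fold lower (5.25 to 6.94). Of 42 keratinocyte differentiation genes, 1 was higher in SCC1, GRHL3 at 2.35-fold (1.76 to 3.15).

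Setting the median log2 fold of listed SCC1 genes, -1.05, to 0 gave 773 higher and 366 lower, 67.9% higher in place of 40.6%. Most listed genes were lower and none had a small difference, so that median falls among the lower genes by construction. The shift can then remove only lower genes, and unlisted genes did not enter it. These counts, and those of the lists after scaling, therefore cannot decide whether the split is sound.

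The second comparison asks the same of FaDu cells. AXL, a receptor tyrosine kinase gene, was 19.6-fold lower (15.3 to 25.4), and the transcription factor gene ETS1 was 11.1-fold lower (9.83 to 12.6), from 292 to 26.2 CPM. NOLC1 was 11.9-fold lower (10.9 to 13.1). The imprinted noncoding RNA H19 was 61.0-fold higher (41.1 to 94.6), going from 2.18 to 133 CPM. The receptor tyrosine kinase gene FGFR3 was 10.7-fold higher (9.41 to 12.1), and KRT13, a keratin of stratified epithelia, was 12.1-fold higher (6.10 to 27.2).

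The table for FaDu lists 1545 genes, 656 higher and 889 lower, with 179 and 189 of them at 4-fold or more. The listed genes are 11.2% of the 13796 that the authors tested. IL1RL1, the receptor gene for interleukin-33, had 296 reads in the control and 2 after FOSL1 siRNA, a ratio of 134 (36.7 to 1109). CPA4 was 17.9-fold lower (9.81 to 36.4), GPR176 16.4-fold lower (8.74 to 34.9) and TMEM200A 16.3-fold lower (7.66 to 41.3). AMMECR1 was 10.2-fold lower (7.0 to 15.5). DUSP6, a phosphatase that limits ERK signalling, was 8.31-fold lower (7.04 to 9.88). The clathrin light chain gene CLTA was 6.68-fold lower (5.69 to 7.88). Among the rises, AKR1B10 was 24.1-fold higher (12.4 to 53.5) and CYP1B1, a cytochrome P450 gene, 21.1-fold higher (14.4 to 32.1). PALM was 11.5-fold higher (7.0 to 20.2), the ephrin receptor gene EPHB3 9.19-fold higher (6.61 to 13.1), and the glycosyltransferase gene A4GALT 7.43-fold higher (5.08 to 11.2). LYPD3 rose from 13.3 to 91.8 CPM and CLEC7A from 2.0 to 17.5 CPM. H3F3A, a histone variant gene with near-identical processed copies, had no reads in the FaDu control and 42.4 CPM after FOSL1 siRNA, at least 162-fold higher but uncertain for that reason.

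Of the 42 keratinocyte differentiation genes, 14 were higher, 1 was lower and 27 were not listed in FaDu. PI3, an elastase inhibitor of stratified epithelia, was 9.97-fold higher (4.29 to 28.3), S100A9 8.13-fold higher (5.50 to 12.4), and TGM1, the transglutaminase of the cornified envelope, 6.96-fold higher (3.94 to 13.3). Of the 26 junction genes, 4 were higher, 2 lower (0 after scaling) and 20 not listed, with TJP3 6.30-fold higher (3.68 to 11.5), CLDN4 3.73-fold higher (3.47 to 4.0) and DSC3 2.21-fold lower (1.97 to 2.49). Of the 15 basal keratinocyte genes, 3 were higher and 3 lower (0 lower after scaling), KRT17 being 3.29-fold higher (3.21 to 3.37) and EGFR 3.0-fold lower (2.82 to 3.19). KRT17 is uncertain because of its near-identical pseudogenes.

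Of the 24 integrin and basement membrane genes, 8 were lower (1 after scaling), 0 higher and 16 not listed in FaDu, with ITGB1 2.93-fold lower (2.80 to 3.07), ITGA3 2.89-fold lower (2.75 to 3.03) and CD44 2.31-fold lower (2.18 to 2.44). Of the 31 proteases and regulators, 10 were lower, 3 higher and 18 not listed, a split that scaling brought to 3 and 3. ADAMTS6 was 9.81-fold lower (4.53 to 25.2), the collagenase genes MMP13 4.03-fold lower (3.82 to 4.25) and MMP1 2.26-fold lower (2.15 to 2.38), and the cathepsin gene CTSL 2.45-fold higher (2.23 to 2.69). MMP9, PLAU, PLAUR and ITGA6 were in neither line's table. Of the 26 genes of epithelial-mesenchymal transition, 5 were lower and 2 higher, with SNAI2 4.26-fold lower (3.48 to 5.25), CDH2 4.13-fold lower (3.38 to 5.07) and S100A4 8.77-fold higher (4.91 to 17.0); scaling brought them to 2 and 2. Of 14 fibroblast markers, 3 were also lower in FaDu (1 after scaling) and 0 higher, among them COL3A1, 3.53-fold lower (2.22 to 5.86), and POSTN, 2.10-fold lower (1.39 to 3.24).

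Of the 23 YAP/TAZ targets, 10 were lower (3 after scaling), 0 higher and 13 not listed in FaDu, with FJX1 3.11-fold lower (2.61 to 3.73) and CYR61 2.96-fold lower (2.76 to 3.17) beside AXL. Of the 27 EGFR ligands and MAPK feedback genes, 7 were lower (4 after scaling), 1 was higher and 19 not listed, PHLDA1 being 4.38-fold lower (4.02 to 4.79) and NRG1 4.35-fold lower (3.76 to 5.06). Of the 24 NRF2 targets, 8 were higher, 1 was lower and 15 not listed, with AKR1C3 8.79-fold higher (5.21 to 15.8) and AKR1C1 5.37-fold higher (4.65 to 6.23). These AKR1C values carry the same uncertainty as in SCC1. UGT1A6, which shares exons with other genes of its locus and is uncertain for that reason, was 4.31-fold higher (3.27 to 5.75). The 8 higher genes thus include AKR1C1, AKR1C2, AKR1C3 and UGT1A6, which are not clearly separate members. GCLM was the lower gene, at 2.12-fold (1.99 to 2.26). Of the 39 interferon-stimulated genes, 7 were higher, 0 lower and 32 not listed, with IFI27 4.61-fold higher (3.47 to 6.20), XAF1 4.17-fold higher (2.41 to 7.59) and IFIT1 3.09-fold higher (2.83 to 3.38). The cytokine list had 6 lower and 5 higher, turning to 3 and 5 with scaling. CSF2 was 6.45-fold lower (3.67 to 12.2), IL1B 6.32-fold lower (5.51 to 7.28), IL24 3.88-fold lower (2.99 to 5.10) and CSF1 4.05-fold higher (3.46 to 4.75). Of the 36 G1/S genes, 2 were lower, CDK6 at 4.57-fold (4.03 to 5.19) and CDC45 at 2.36-fold (2.03 to 2.76), and CCNE1 was 1.95-fold higher (1.59 to 2.41); no G2/M gene was listed. Of the 31 hypoxia genes, 2 were higher and 2 lower (0 lower after scaling), EGLN3 being 3.52-fold higher (2.93 to 4.25). The share of all tested genes that were listed in FaDu would give 3.47 hypoxia genes and 4.03 G1/S genes.

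Setting the median log2 fold of the listed FaDu genes, -1.01, to 0 gave 656 higher and 342 lower, 65.7% higher in place of 42.5%. As in SCC1, that median lies among the lower genes because most listed genes were lower and small differences were filtered out. These counts cannot decide on the split either.

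**Figure D2:**
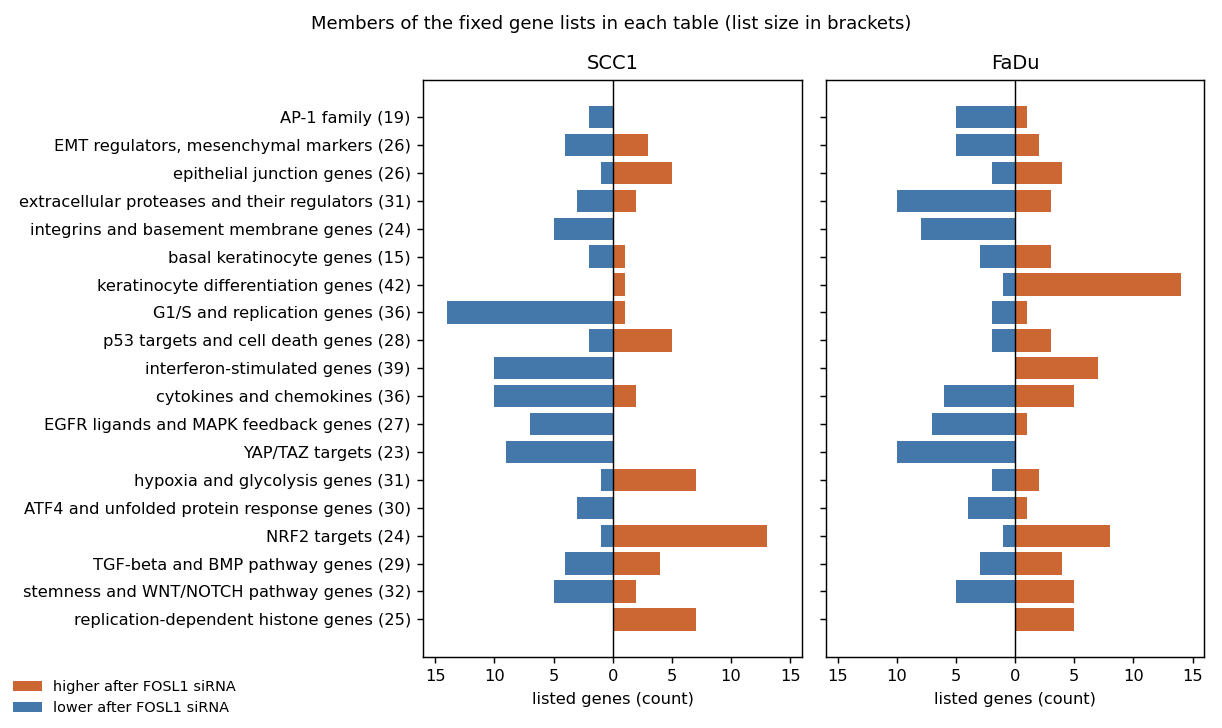
Number of members of each fixed gene list that were higher (orange, right) or lower (blue, left) after FOSL1 siRNA in SCC1 and FaDu, for lists with at least 5 listed members in either line. Of the listed NRF2 targets, 13 of 14 in SCC1 and 8 of 9 in FaDu were higher. Both counts include AKR1C genes and UGT1A6, whose separate values are uncertain. The listed interferon-stimulated genes were 10 lower in SCC1 (3 after scaling to the median fold) and 7 higher in FaDu. That scaling, which can remove only lower genes, turned the majority of the transition list in SCC1 and of the cytokine list in FaDu.

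The third comparison asks how far both lines share these differences. FOSL1, NOLC1, CPA4, AXL, AMMECR1, IL1B, LTB and ETS1 led the genes that were lower in both lines, ranked on log2(CPM + 1) by the smaller of their 2 differences among genes reaching 5 CPM in both. LTB, the lymphotoxin beta gene, was 8.01-fold lower in SCC1 (5.70 to 11.6) and 8.13-fold lower in FaDu (5.17 to 13.4), and ETS1 was 5.59-fold lower in SCC1 (4.87 to 6.44). AMMECR1 was 7.70-fold lower in SCC1 (6.20 to 9.68). CLEC7A, AKR1C3, AKR1C1, H3F3A, LYPD3, SCML2, CYP1B1 and PALM led the genes that were higher in both, by the same rule. SCML2, a Polycomb group gene, was 5.35-fold higher in SCC1 (4.10 to 7.06) and 5.47-fold higher in FaDu (4.65 to 6.48).

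In SCC1, LYPD3 was 4.94-fold higher (4.16 to 5.91), CYP1B1 4.98-fold higher (3.83 to 6.54) and PALM 5.43-fold higher (3.84 to 7.85). H3F3A was 5.25-fold higher in SCC1 (4.64 to 5.96), with the same uncertainty as in FaDu. In all, 678 genes were listed in both lines, 35.6% of the SCC1 genes and 43.9% of the FaDu genes. Independent lists among the 13796 genes that the authors tested in each line would share 213. That number takes each tested gene as equally likely to be listed, whatever its coverage. Genes well covered in both lines may be listed together more often than that. Of the 678, 227 were higher in both, 428 lower in both and 23 opposite, so 96.6% had the same direction, against 54.4% from the splits of the shared genes alone. Across these genes, which are not independent replicates, the log2 folds had a Pearson r of 0.82. Each gene passed the authors' filter in both lines, so none lies near 0 and this r largely restates the shared directions. Genes that moved oppositely included PCDH7, 2.16-fold higher in SCC1 (1.94 to 2.42) and 6.07-fold lower in FaDu (4.27 to 8.87), and PRSS22, 3.86-fold higher in SCC1 (3.16 to 4.74) and 2.11-fold lower in FaDu (1.88 to 2.38). All 8 NRF2 targets, all 6 YAP/TAZ targets and all 4 integrin and basement membrane genes listed in both lines had the same direction in both. The 8 NRF2 targets include AKR1C genes and UGT1A6, whose separate values are uncertain. The same held for all 5 transition genes, all 5 cytokine genes and all 5 EGFR and MAPK genes listed in both. With 96.6% over all shared genes, such agreement in small sets is not particular to these lists. The direction was the same for 4 of 5 junction genes, 2 of 3 hypoxia genes and 0 of 1 interferon-stimulated genes.

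**Figure D3:**
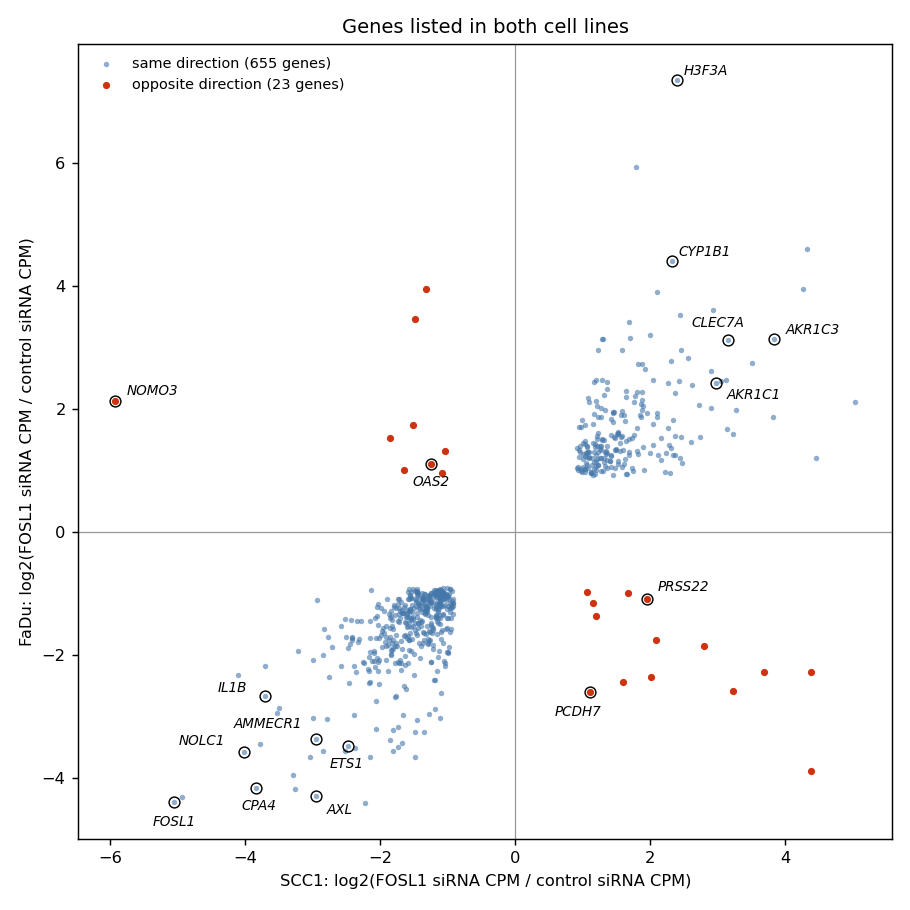
log2 fold (FOSL1 siRNA over control siRNA) in SCC1 on the horizontal axis and in FaDu on the vertical axis for the 678 genes listed in both lines, with named genes ringed and genes at 0 reads placed at a floor of 3 reads. The 655 genes with the same direction (blue) lie at the lower left and upper right, and the 23 opposite genes (red) in the other quadrants.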

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

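The tests of shared copies, of readthrough models and of a response to transfected RNA were chosen after their results were seen. The differences between lines in this part were not tested, since each line has 1 library per group.

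The interferon-stimulated genes listed in each line lay on opposite sides: the 10 listed in SCC1 had a median log2 fold of -1.40 and the 7 listed in FaDu 1.51, a difference of -2.90 between sets that share 1 gene, with the other members of the 39 not listed. OAS2, that shared gene, was 2.38-fold lower in SCC1 and 2.14-fold higher in FaDu, a log2 difference of -2.35. Different scaling of the tables would shift the shared genes as a whole, yet their median log2 difference, SCC1 minus FaDu, was -0.0456. A response to transfected RNA stays open: that 0% of the 10 were higher in SCC1 restates the pattern, and the control libraries also received siRNA. A difference between the cell lines, or between these single libraries, also remains an untested candidate explanation.

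Genes at 0 reads in 1 library of a line and well covered in the other form a second pattern. NOMO3, one of several near-identical copies, differed most among the 8 opposite genes named, with a log2 difference of -8.06 at the floor, from 16.2 to 0 CPM in SCC1 and from 6.45 to 28.4 CPM in FaDu. In SCC1, SMN1 and SMN2 changed far in opposite directions while their sum went from 79.4 to 92.2 CPM, a ratio of 1.16, which fits reads being divided between copies. Readthrough models, which share exons with their neighbours, made up 28 of the 68 entries at 0 in 1 library (41.2%) and 23 of the other 3380 (0.680%), over both tables with a gene listed in both lines counted in each, a ratio of 60.5. How reads were assigned to such genes may therefore account for many of these values, while the remaining genes at 0 were not tested one by one.

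The other genes with opposite directions, chosen by the rule for named genes, are given as log2 differences, SCC1 minus FaDu. Of the 8 named, NOMO3 alone had an FDR under 0.05 in both lines in the authors' deposited table; for RHOBTB3, DSC3, OAS2 and NDRG1 that table gave an FDR above 0.05 in both lines, for LOC727751 and PCDH7 in SCC1, and for PRSS22 in FaDu. LOC727751 differed by -3.24, and was lower in SCC1 and higher in FaDu. RHOBTB3 differed by 2.55, from 70.8 to 162 CPM in SCC1 and from 7.67 to 2.99 CPM in FaDu. The desmosomal cadherin gene DSC3 differed by 2.30, from 16 to 35.7 CPM in SCC1 and from 86.9 to 39.3 CPM in FaDu. PCDH7 differed by 3.72 and PRSS22 by 3.03, both higher in SCC1 and lower in FaDu. NDRG1, a hypoxia-responsive gene, differed by 2.04, and its fall in FaDu lost its sign when scaled to the median fold.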

How the results depend on the processing

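The FDR limit of 0.05, the count test at other dispersions and the omission of genes at 0 reads and readthrough models were chosen after seeing the data. Counts of genes kept their order of more lower than higher genes under each alternative except the scaling. The authors' p-value under 0.01 left 946 genes in SCC1 (373 higher, 573 lower) and 781 in FaDu (341, 440). The authors' FDR under 0.05 left 521 (216, 305) and 393 (172, 221), and an FDR under 0.01 left 250 (111, 139) and 225 (104, 121). The count test at a dispersion of 0.1 left 913 (361, 552) and 781 (343, 438), and at 0.16 it left 483 (207, 276) and 461 (215, 246). These drops follow from the stricter limits. No group holds replicates from which to estimate the dispersion.

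Scaling to the median fold left 1139 genes in SCC1, 366 of them lower, and 998 in FaDu, 342 lower. The log2 fold of FOSL1 became -4.00 in SCC1 and -3.37 in FaDu. The sign turned for SNAI2 (0.00225), DLGAP5 (0.00343) and TOP2A (0.0584) in SCC1 and for DDIT4 (0.0124) and NDRG1 (0.0327) in FaDu, all close to 0, as the scaling itself shifts each log2 fold by about 1. It also left as many higher as lower genes in the basal keratinocyte, G1/S and stemness lists of SCC1 and in the AP-1, transition, protease, G1/S and ATF4 lists of FaDu. It turned even splits to 5 higher and 1 lower for stemness genes, 3 and 0 for basal keratinocyte genes and 2 and 0 for hypoxia genes in FaDu. It removes lower genes and no higher ones by construction.

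Of the genes shared by both lines, scaling left 347 (335 in the same direction, 12 opposite), and an FDR under 0.05 in both left 145 (139, 6). Opposite genes numbered 12 at 5 CPM or more and 15 without genes at 0 reads and readthrough models. At the authors' FDR under 0.05, 65 of 142 listed list members stayed in SCC1 and 63 of 149 in FaDu, with a gene in several lists counted once here. None stayed for the G2/M, ATF4, cholesterol, antigen presentation and keratinocyte differentiation lists of SCC1, nor for the histone, cholesterol and antigen presentation lists of FaDu. The minimum of 1 CPM could change no count, since the higher library of every listed gene already reached it. The fold of 2 moved 4 of the counts per list and direction beyond 1.5 times. It kept the counts of listed, shared and list-member genes within 1.5 times. So did the pseudocount of 1 CPM for listed and shared genes, that of 0.1 CPM and summed symbols for listed genes, and older symbols for list members; no symbol occurred more than once. The pseudocount of 1 CPM moved 17 folds of named genes beyond their counting interval or bound, with no change of sign, for example CSF3 in SCC1 to a log2 fold of -3.84, IL1RL1 in FaDu to -4.49 and PI3 in FaDu to 2.03. A fit with the line as a block would leave 1 residual degree of freedom over the 678 shared genes; it was not made, since these genes were selected by the authors' p-values in both lines and stand in separate tables. Depth limits genes near 1 CPM most, where 1 read is worth 0.0755 to 0.0965 CPM.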

Other observations

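Several gene lists have not been described above. As before, scaling to the median fold can remove only lower genes, so counts after it do not decide on a list's direction. Of 25 replication-dependent histone genes, 7 were higher in SCC1 and 5 in FaDu, 0 were lower and the others were not listed; the higher ones included HIST1H2BD, 4.86-fold higher in SCC1 (3.63 to 6.61) and 2.66-fold in FaDu (1.71 to 4.22), and HIST1H2BK, 2.43-fold (2.21 to 2.67) and 2.81-fold (2.27 to 3.5). Histone genes are near-identical copies, so single values are uncertain. Of 28 p53 targets and cell death genes, 5 were higher and 2 lower in SCC1, and 3 higher and 2 lower in FaDu, with 0 lower in either line after scaling to the median fold. BTG2, an antiproliferative gene, was 4.28-fold higher in SCC1 (3.35 to 5.51) and 3.66-fold in FaDu (2.70 to 5.03), while GADD45A was 2.49-fold lower (2.22 to 2.80) and 2.88-fold lower (2.53 to 3.29). Of 29 TGF-beta and BMP pathway genes, 4 were higher and 4 lower in SCC1, and 4 higher and 3 lower in FaDu, with FST, the gene of the activin antagonist follistatin, 5.52-fold lower (4.32 to 7.14) and 5.50-fold lower (4.53 to 6.72). Of 32 stemness and WNT/NOTCH genes, 2 were higher and 5 lower in SCC1 (2 lower after scaling), and 5 higher and 5 lower in FaDu (1 lower after scaling), with the WNT antagonist gene DKK1 4.47-fold lower (4.11 to 4.87) and 4.10-fold lower (3.61 to 4.67), and SOX9 5.39-fold lower (3.67 to 8.14) and 2.70-fold lower (2.20 to 3.34).

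Of 27 Mediator, BET and cofactor genes, 3 were lower in SCC1 (0 after scaling) and 2 in FaDu (1 after scaling), with MED15 2.99-fold lower (2.71 to 3.31) and 3.37-fold lower (2.92 to 3.89). MT2A, with near-identical copies and so uncertain, was the listed member of 13 metallothionein genes, 2.89-fold lower (2.75 to 3.05) and 3.35-fold lower (3.21 to 3.49), and passed 1.5-fold after scaling in FaDu but not in SCC1. Of 30 ATF4 and unfolded protein response genes, 3 were lower in SCC1 (0 after scaling), ASNS at 2.73-fold (2.41 to 3.09) among them, and 4 were lower (1 after scaling) and 1 higher in FaDu, where DDIT3 was 3.26-fold lower (2.46 to 4.37). Of 30 cholesterol and fatty acid synthesis genes, HMGCS1 and INSIG1 were higher in SCC1, at 2.64-fold (2.42 to 2.88) and 2.66-fold (2.38 to 2.98), and LSS was 2.28-fold lower in FaDu (1.92 to 2.71); 0 were lower after scaling. Of 22 antigen presentation genes, 1 was higher and 1 lower in SCC1 and 1 was lower in FaDu, where TAPBP was 2.55-fold lower (2.33 to 2.80). After scaling, 0 were lower in either line. The listed share of all tested genes would give 3.72 Mediator genes in SCC1 and 3.02 in FaDu. It would give 4.14 and 3.36 for the ATF4 and the cholesterol list, and 3.03 and 2.46 for antigen presentation. Among these lists, only the ATF4 list in FaDu lay above that number. It counts every list member as tested, which is not known, so it may be too high. None of 40 ribosomal protein genes, 15 mitochondrially encoded genes or 10 endothelial markers was listed. None of 14 fibroblast markers was listed in SCC1. Of 16 leukocyte markers, CD68 was lower in both lines, at 4.34-fold (3.14 to 6.11) and 4.26-fold (3.37 to 5.43), and CD14 was 2.55-fold higher in FaDu (1.64 to 4.05).

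The tests of agreement between the lines in this paragraph were fixed before their results were seen. That 96.6% of the shared genes had the same direction may reflect a shared response, and 2 technical explanations were set against it. With genes cut into 5 bins, the tests assumed that a trend with GC content or transcript length has no sign in the middle bin. There, 95.5% of the shared genes had the same direction for GC content and 96.9% for length. Agreement was 95.5% to 98.5% across the GC bins and 94.7% to 98.5% across the length bins. The middle bin thus did not stand apart, and it was not shown to be neutral, so these values decide neither explanation. At 50 CPM or more in both lines, 202 of the 204 shared genes (99.0%) had the same direction; few reads lower such agreement and cannot create it, so this value decides nothing. Off-target effects of a siRNA used in both lines would give the same pattern and remain open, as the sources used here give no siRNA sequence. GC content did go with the direction within each line, a trend that was not among those fixed tests. The share of higher genes from the lowest to the highest GC bin was 34.5%, 33.2%, 39.7%, 45.9% and 49.7% in SCC1 and 40.4%, 37.5%, 37.7%, 46.2% and 51.3% in FaDu. In both lines it was lowest in the second bin and rose at each step from there.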
